A study of Mus musculus with 2 samples.

How the data were processed

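Bone marrow cells of C57BL/6 mice were cultured for 4 days with GM-CSF only or with GM-CSF plus IL-6, and RNA was isolated with a mirVana kit, per the labels' protocols. From each culture 0.2 ug of RNA was labelled with Cy3. The labels name a linear amplification kit for cRNA at this step, which is a kit for mRNA arrays; whether it was the one used for these miRNA arrays is not given in the sources used here. The groups came from the treatment in the labels, with 1 array each, and both arrays lay on the same slide and in the same scan, so neither could be tested as a batch.

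Per the file headers, the authors' scanner files are the output of Agilent Feature Extraction 10.7.1.1 for 1 colour, and their values are background-subtracted, spatially detrended intensities with no scaling between arrays. Each of the 1080 miRNA names (1023 mouse and 57 viral) was measured on 40 spots per array, shared among 2780 probes in total. There were 0 saturated spots, and the median coefficient of variation of replicate spots was 8.18% for GM-CSF plus IL-6 and 7.42% for GM-CSF only, per the file headers. The authors' deposited value table holds log2 values. For all 308 and 301 detected miRNAs these equalled, within 0.2%, the log2 sum of the probe totals over 3 times their deposited errors, minus 1 constant per array (6.28 and 6.28). Undetected miRNAs sit at a floor. The column medians were -9.60 and -9.60. The scale and direction of the table are known from that match, and the origin of the constants stays unknown.

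The level of a miRNA was the sum of the deposited total probe signals over its probes. The design, fixed before the data were examined, named the deposited gene-total intensity as equal to that sum, and it was not. For 75 detected miRNAs on the GM-CSF plus IL-6 array and 71 on the GM-CSF only array, the gene total exceeded the sum of the detected probes, and in all 146 cases the excess equalled, within 0.2%, the gene total of the preceding detected miRNA in name order. The probe sum was therefore used, and the gene total became an alternative chosen after seeing the data. A miRNA counted as detected by the scanner software's flag. Each array was divided by its 75th percentile over the 292 miRNAs detected on both arrays (160 and 182), and the log2 ratio was taken as GM-CSF plus IL-6 over GM-CSF only. Spot errors came from replicate spots without outlier flags. For miRNAs detected on 1 array only, the bound set the bright array's scaled value against the higher of the dim array's lowest detected value and the miRNA's own value there. Where the own value was the higher, the result is a ratio under this scaling and not a lower limit. A bound against the lowest detected value is no firm limit either, since detection did not follow signal alone. On the GM-CSF only array miR-448-5p was undetected at a signal of 9.03, above the lowest detected signal of 3.73.

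No test was run between the groups. A fixed size rule, at least 2-fold, took its place, and lists of miRNAs fixed before the data were examined were described by their median and its percentile among 10000 random lists of the same size, matched in 10 bins of mean level. Lists with under 3 members detected on both arrays have values only. Of 277 list entries, 252 matched a name on the array exactly and 17 through synonyms in a RefSeq gene table (GRCm38.p6, used for names only). The other 8 are not analysed here. Names are those of the array's design and can be old.

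The rule for named miRNAs, also fixed before the data were examined, took up to 12 in each direction with an absolute log2 ratio of at least 1, a level at or above the median and all probes changed the same way, which 0 miRNAs met. It further took up to 5 in each direction with the largest bound of at least 2-fold, the 5 brightest of each array, the 2 brightest and the 2 with the largest absolute log2 ratio of each list, and 6 miRNAs fixed by name: miR-155-5p, miR-21-5p, miR-146a-5p, miR-223-3p, miR-142-3p and miR-214-3p.

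The alternatives were scaling by the 75th percentile over all miRNAs, by the median, by none, by quantile normalization or by loess (span 0.7), the mean log2 spot signal (floor 1), normexp with an offset of 50, the authors' table, stricter detection, the brighter miRNAs alone, miRNAs without outlier spots, and odd or even spots. Other fold thresholds, and the counts without the Sfmbt2 cluster, were also tried. The gene totals, mouse names alone and scaling by 4 control probes (names starting dmr) were added after seeing the data, as was the ranking of lists against random lists under each alternative. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used. The functions were tested on simulated data for the GM-CSF plus IL-6 over GM-CSF only comparison, with spots drawn for the 292 miRNAs from real probe means and spot SDs. Simulated ratios were first centred on the median of the miRNAs known to be unchanged. All 20 miRNAs changed 2.5-fold and all 20 changed 4-fold then passed the 2-fold rule, and 0 of 212 unchanged miRNAs did. The real 2-fold counts had no such centring, so the simulation does not test the effect of an offset between the arrays. The simulation covers spot error only.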

Results

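MicroRNA levels were measured in myeloid-derived suppressor cells (MDSCs), immature myeloid cells that restrain T cells, grown from the bone marrow of C57BL/6 mice. The marrow cells were kept for 4 days in medium with 5% serum and 40 ng/ml GM-CSF, a growth factor for myeloid cells, either alone or together with 40 ng/ml IL-6, an inflammatory cytokine. Each condition had 1 single-colour Agilent array, so the comparison has no replicate check and carries no p-value. The errors given with the ratios are standard errors over replicate spots within the arrays and cover spot error only. Of 1080 miRNA names on the array, 308 were detected in the culture with GM-CSF plus IL-6 and 301 in the culture with GM-CSF only, with 292 detected in both. The precision is limited by the number of arrays.

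Of 9 names of the myeloid list on the array, 5 were detected on both arrays and 4 on neither (miR-223-5p, miR-511-3p, miR-511-5p and miR-322-3p), and their signals ranged widely. Among the brightest miRNAs was miR-223-3p, which is highly expressed in granulocytes and their precursors, with a summed signal of 6239 in GM-CSF plus IL-6 and 6807 in GM-CSF only. The widely expressed miR-21-5p followed at 5502 and 6488, and the blood-cell miRNA miR-142-3p stood at 1398 and 1460. The dimmest detected member of the myeloid list, miR-338-3p, had 24.2 and 25.7. The brightest name on either array was miR-1937b_v16.0, with 40289 and 41404, or 29.6% of the detected signal on each array. The other names among the 5 brightest of either array were miR-466i-5p (17953 and 17305), miR-574-5p (8070 and 7879) and miR-720 (6466 and 6491). The 10 brightest miRNAs held 72.7% of the detected signal with IL-6 and 72.4% without it. The sources used here do not settle whether miR-1937b_v16.0 and miR-720 are miRNAs or fragments of tRNA, so these shares are of signal under the array's names.

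The comparison that the design implies asks how the addition of IL-6 to GM-CSF altered the miRNAs of these cells. Most levels were close: 276 of the 292 miRNAs, or 94.5%, lay within 1.5-fold between the cultures. At least 2-fold higher with IL-6 were 4 miRNAs, and 0 were at least 2-fold lower. All 4 were dim, with summed signals between 11.3 and 39.6 on either array. Among the 146 miRNAs at or above the median level, 0 reached a 2-fold difference and 6, among them 1 viral name, were at least 1.5-fold higher with IL-6.

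The 4 miRNAs, named here after their values were seen, were miR-466h-3p, miR-1927, miR-504-3p and miR-3070b-3p. The signal of miR-466h-3p was 39.6 with IL-6 and 11.3 without it, a log2 ratio of 1.99 ± 0.07 (spot SE). For miR-1927 the signals were 25.2 and 11.7 (1.29 ± 0.06), for miR-504-3p 29.0 and 14.3 (1.20 ± 0.05), and for miR-3070b-3p 22.7 and 11.9 (1.11 ± 0.07). Every probe of each of the 4 was higher with IL-6. Scaling by the median instead lowers every log2 ratio by the same amount, and the 4 values became 1.79, 1.08, 0.99 and 0.91 with the same spot errors, so that 2 stayed past 2-fold. Normexp background correction with an offset of 50 draws ratios of dim miRNAs toward 0 by construction, and the folds were 1.51, 1.28, 1.28 and 1.23.

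The median log2 ratio of the 292 miRNAs was 0.12 after scaling by the 75th percentile and moved between -0.15 and 0.12 under other settings that kept all 292. It was 0.13 for the 18 miRNAs without outlier spots. Ratios of groups and of single miRNAs are therefore given below relative to that median, as relative log2 ratios. Bounds for miRNAs detected on 1 array only stay on the scale of the 75th percentile. Scaling by the 75th percentile over all miRNAs, by the median, by none or by the dmr controls shifts every miRNA alike. These uniform scalings cannot change a relative value. On this relative scale 3 miRNAs were at least 2-fold higher with IL-6, and 10 instead of 16 at least 1.5-fold higher. Of those at or above the median level, 2 instead of 6 were at least 1.5-fold higher. Of 13 lists ranked against random lists, with no correction for their number, 1 lay above and 3 below the central 95%.

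**Figure D1:**
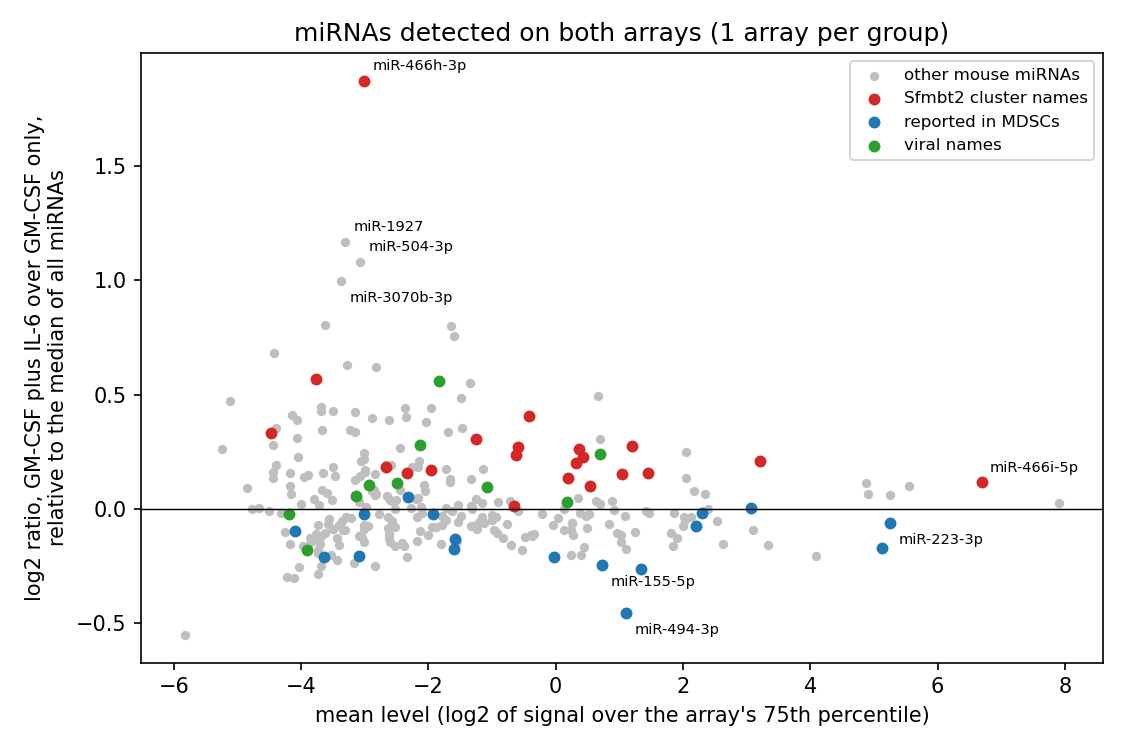
Each point is 1 of the 292 miRNAs detected on both arrays. The horizontal axis is its mean level (log2 of summed signal over the array's 75th percentile) and the vertical axis its log2 ratio of GM-CSF plus IL-6 over GM-CSF only, relative to the median of all; miR-466h-3p is highest at 1.87, and miR-494-3p stands at -0.46.

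Names starting miR-297, miR-466, miR-467 or miR-669, the name families of the multicopy miRNA cluster in an intron of Sfmbt2, were higher with IL-6 as a group. Members were taken by name alone and their genomic positions were not checked, so some may lie outside Sfmbt2. The term Sfmbt2 cluster stands for these names throughout. All 21 members detected on both arrays lay above the median of all miRNAs, with a median relative log2 ratio of 0.21. That median was at percentile 100 among 10000 random lists matched on level, whose central 95% ran from -0.09 to 0.05. Examples were miR-669n (1658 with IL-6 and 1499 without, 0.21), miR-669a-5p (14.98 and 10.6, 0.57) and miR-466i-5p (0.12). Members of these name families can be similar in sequence, so their probes can share signal and the group does not count as 21 independent measurements. How similar the 21 are was not examined. When miRNAs with any outlier spot were left out, 1 member remained and the group value was -0.0011.

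Another 5 names of the cluster were detected with IL-6 only and 0 with GM-CSF only. Of these, miR-467f was 3.71-fold and miR-669p-3p 3.40-fold higher after scaling against their own undetected values, which are ratios and not lower limits. For miR-466g the bound against the dim array's lowest detected value was 3.40-fold. Outside the cluster, miR-574-3p was 4.52-fold higher against that same value, with signals of 14.8 and 2.90. Neither is a firm lower limit, since miR-448-5p was undetected on the dim array at a signal of 9.03. A name of mouse cytomegalovirus, mcmv-miR-m01-2, was 3.92-fold higher against its own undetected value, again a ratio and not a lower limit. In all, 16 names were detected with IL-6 only and 9 with GM-CSF only. Of the 16, 9 had a bound of at least 2-fold, and of the 9 in the other direction 0 did.

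Measured beside these, 8 of the 10 viral names detected on both arrays also lay above the median of all miRNAs. Their median relative log2 ratio was 0.10, at percentile 88.0 among random lists matched on level.

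miRNAs that have been reported in MDSCs were slightly lower with IL-6 as a group, relative to the median of all miRNAs. Under the main scaling and before that median was subtracted, their median log2 ratio was -0.012. Of 17 members detected on both arrays, 15 lay below the median of all miRNAs, and the median relative log2 ratio was -0.13. This was at percentile 0.025 of random lists matched on level, whose central 95% ran from -0.09 to 0.10. Under 15 alternatives the median ran from -0.16 to -0.06, the latter after normexp, and it lay below the central 95% of random lists drawn under the same alternative in all 15. The uniform scalings among the 15 repeat the reported value by construction and are no separate check. The member furthest down was miR-494-3p, with signals of 307 with IL-6 and 441 without it and a relative log2 ratio of -0.46. The value was -0.17 for miR-21-5p, -0.06 for miR-223-3p and 0.05 for miR-181b-5p. Quantile normalization gives miR-21-5p no direction, since its rank of 6 on both arrays sets its ratio to 0. For miR-181b-5p the lowest value under any alternative was -0.02.

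The inflammation-linked list shares 3 detected members with that group. Its 7 detected members had a median relative log2 ratio of -0.12, at percentile 1.5, and 5 of the 7 lay below the median of all. Before the median of all was subtracted, the list median was -0.005. Its best-known members are miR-155-5p, which is induced in activated myeloid cells, and miR-146a-5p, a brake on NF-kB signalling. The signals of miR-155-5p were 254 with IL-6 and 315 without it (-0.25), and those of miR-146a-5p were 53.4 and 61.1 (-0.13). For miR-132-3p the relative log2 ratio was 0.03 and for miR-21-3p 0.16. Under quantile normalization the median of the list was -0.00039. Against random lists under the same alternative the list lay below the central 95% in 12 of 15 and inside it in 3 (quantile normalization, normexp and even spots). The 12 include the uniform scalings, which repeat the reported value by construction.

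The miR-30 family was the remaining list below its random range. Its 5 detected members had a median of -0.10 (0.02 before the median of all was subtracted) at percentile 0.36. All 5 lay below the median of all. The list median is the value of miR-30a-5p, which the MDSC list also holds and which was dim (9.40 and 10.5, spot SE 0.09). Under 15 alternatives the median ran from -0.10 to -0.02, below the central 95% of random lists in 8 and inside it in 7. The 8 were the uniform scalings, which repeat the reported value by construction, loess, even spots, the gene totals and mouse names alone. Among alternatives that could differ, more lay inside the range than below it. Relative log2 ratios were -0.13 for miR-30b-5p and -0.11 for miR-30e-5p, and -0.002 for miR-30d-5p, which went both ways between alternatives.

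**Figure D2:**
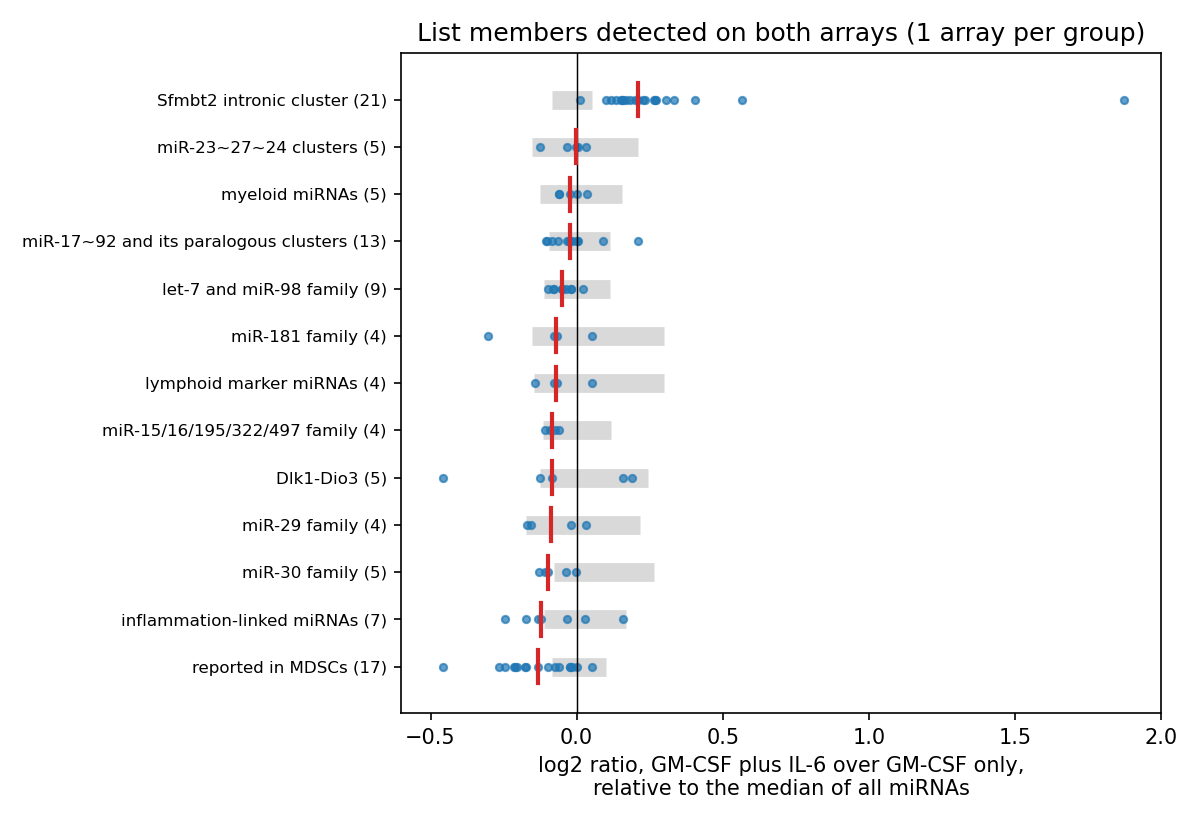
Each blue point is a list member detected on both arrays, placed by its log2 ratio of GM-CSF plus IL-6 over GM-CSF only relative to the median of all 292 miRNAs. Red marks are list medians, grey bars the central 95% of random lists matched on level, and the number of members is in parentheses; the Sfmbt2 cluster median of 0.21 lies above its bar and the median of miRNAs reported in MDSCs, -0.13, below its bar.

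The other 9 lists with at least 3 detected members lay within their random ranges, with medians from -0.09 to -0.004. The myeloid list had a median of -0.02 over 5 members, with miR-142-3p at 0.002 and miR-142-5p at 0.03, and all 3 values went both ways between alternatives. The 13 detected members of the miR-17~92 clusters, which promote proliferation of blood progenitors, had a median of -0.02 (0.03 under quantile normalization, where the middle member has equal ranks on the arrays). Among them were miR-19b-3p at 0.001 and miR-20a-5p at -0.02, which went both ways between alternatives, and miR-18b-5p at 0.21. The median was -0.05 for the 9 members of the let-7 and miR-98 family, -0.004 for the 5 members of the miR-232724 clusters (7 alternatives above 0 and 8 below, the uniform scalings among the 8) and -0.08 for the 4 of the miR-15/16 family. It was -0.09 for the 4 of the miR-29 family, -0.07 for the 4 of the miR-181 family and -0.09 for the 5 of the imprinted Dlk1-Dio3 cluster, which was above 0 under 2 alternatives. The lymphoid markers had a median of -0.07 over 4 members, among them miR-150-5p at 54.2 with IL-6 and 62.6 without.

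Markers of other cell types were mostly below detection or dim on both arrays. Of 4 erythroid names measured, miR-451 alone was detected on both, at 8.10 and 10.4. Of 12 stromal names, miR-214-5p was detected on both (41.3 and 40.9), and miR-214-3p was detected on neither array. Of 7 epithelial names, 2 were detected on both, miR-200c-3p (12.4 and 14.99) and miR-141-3p (8.51 and 7.80). The muscle list had miR-206-3p (67.8 and 55.5, relative log2 ratio 0.35) as its 1 detected member. The neural list had miR-128-3p (24.6 and 23.1) and miR-219-5p (11.3 and 10.69), and the liver list miR-122-5p (11.5 and 9.15) and miR-192-5p (16.9 and 18.1). The megakaryocyte and endothelial list had miR-126-3p (11.0 and 12.8) and miR-10a-5p (51.5 and 61.0), the latter also in the MDSC list. The relative log2 ratio of the lymphoid miR-150-5p was -0.14, and medians were -0.30 for the erythroid list and -0.16 for the megakaryocyte and endothelial list. They were 0.15 for the neural list, and 0.08 for the stromal, 0.18 for the liver and -0.01 for the epithelial list, which 3 went both ways between alternatives. Lists with 1 or 2 detected members were not ranked. Among lists with under 3 detected members, the miR-34 family had miR-34a-5p at 152 and 184, a relative log2 ratio of -0.21. In a further cluster miR-221-3p stood at -0.03 and miR-222-3p at -0.11, and the miR-99/100 and miR-125 family had miR-99b-3p at 0.15 (at lowest -0.03 under alternatives) and miR-125a-3p at -0.14.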

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

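All tests weighed in this part were chosen after the results they bear on had been seen, and the comparison has 1 array per culture.

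Signal outside the main measurement appeared on the viral names of the array: 10 of them were detected on both arrays, although no virus is named in the labels. The brightest was mghv-miR-M1-2-5p, a name of murine gammaherpesvirus, with signals of 293 with IL-6 and 260 without. A further 2 viral names were detected with IL-6 only. The signals of mcmv-miR-m01-2 were 15.6 and 4.53, with 17 of 40 spots well above background with IL-6. After scaling it was 3.92-fold higher against its own undetected value, a ratio and not a lower limit. The signals of mghv-miR-M1-11-5p were 10.9 and 3.13, with 0 of 40 spots well above background on either array. After scaling it was 3.32-fold higher against the dim array's lowest detected value, which is no firm lower limit. No biological explanation for the viral names was tested.

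The Sfmbt2 cluster names were higher with IL-6 as a group. The level of the members was argued against as the cause. Their median log2 ratio of 0.33 lay above the random lists of matched level, whose upper limit was 0.17 on the same scale. A uniform scaling error shifts the cluster and the random lists alike, so the comparison cannot test it. Nor can such an error set the cluster apart from other miRNAs. Signal on repetitive probes that does not come from mouse miRNAs may contribute, and the viral names were set beside the cluster for that reason. Their median log2 ratio was 0.22, above the 0.12 of all miRNAs but inside the range of random lists. Of the 2 viral names detected with IL-6 only, 1 had spots well above background (3.92-fold after scaling) and the other (3.32-fold) had none. In the cluster 5 names were detected with IL-6 only. Probe sequences were not examined and the viral names were not chosen for repetitive probes, so these values cannot decide for or against it. That explanation stays open, and so does an effect of IL-6, which 1 array per culture cannot test.

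The miRNAs reported in MDSCs were lower with IL-6 than miRNAs of like level. A class effect of well-known miRNAs was argued against as the whole cause. Among random lists drawn from the 80 detected members of all lists but the Sfmbt2 one, the median was at percentile 0.03. That pool, which holds the 17 members themselves, had a median relative log2 ratio of -0.04. Its other 63 members had -0.03, against -0.13 for the MDSC list. The class thus lay slightly lower, which may make up part of the difference. With each member left out in turn, the highest relative median was -0.11. Dropping any member of 17 can move a median only between neighbouring middle values. That result therefore cannot decide for or against a single member as the cause. Single detected markers of other cell types went both ways by as much, from -0.30 for miR-451 to 0.39 for miR-122-5p. The difference is small, and variation between cultures stays open beside an effect of IL-6 and could account for it.

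The 4 miRNAs at least 2-fold higher with IL-6 were all dim. Spot error was small beside their log2 ratios, the smallest of which was 16.02 times its spot standard error. That says little as a test, since they were selected for a log2 ratio of at least 1. The median spot standard error of all miRNAs was 0.04, so passing was close to given. A single deviating probe was argued against, since all 4 were higher on every probe. Variation between arrays of dim signal may account for them: the highest log2 ratio of a viral name detected on both arrays was 0.68, and 10 such names are too few to set a limit. Of the 2 dim viral names detected with IL-6 only, 1 was 3.92-fold higher after scaling and goes with this explanation. The other (3.32-fold) had no spot well above background. That explanation stays open, and so does an effect of IL-6.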

How the results depend on the processing

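The deposited gene totals, mouse names alone and control-probe scaling were chosen after seeing the data. So was the relative scale: on the absolute scale 141 of the list medians and 419 of the values of named miRNAs across alternatives moved by more than the spot SD or reversed, against 8 and 23 relative to the median of all miRNAs. Part of that drop is built in, since the uniform scalings cannot move a relative value. The median itself was 0.12 as reported, -0.15 with the 75th percentile over all miRNAs, -0.09 with median scaling and -0.06 with none. No paired analysis was possible because each group has 1 array and they share 1 replicate number.

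Against 4 miRNAs at least 2-fold higher and 0 lower, the count higher was 2 with the 75th percentile over all miRNAs, 2 with median scaling, 2 with dmr control scaling and 0 with normexp, whose offset shrinks dim ratios by construction. It was 0 with at least 50% of spots well above background, 0 among the brighter miRNAs and 0 without outlier spots, which says nothing about the 4, since none of them was among the 220, 146 and 18 miRNAs left. The authors' value table gave 7 higher, all of the 4 among them, and 1 lower. The deposited gene totals gave 6 higher, 2 of them among the 4, and 5 lower. The 1.5-fold threshold gave 16 higher (10 relative to the median of all) and the 4-fold threshold 0. Of miRNAs detected on 1 array only, requiring all spots against none well above background left 0 with IL-6 and 0 with GM-CSF only, and a bound of at least 2-fold left 9 and 0.

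Relative list medians that moved were, under quantile normalization, -0.00039 for the inflammation-linked list and -0.088 for the miR-34 family; under normexp, 0.18 for the muscle markers and 0.12 for the Sfmbt2 cluster; under the deposited gene totals, -2.62 for the erythroid markers, whose 1 member miR-451 had gene totals of 17.7 and 115 against probe sums of 8.10 and 10.4. The Dlk1-Dio3 cluster had -0.44 in the brighter miRNAs and 0.18 without outlier spots, and the Sfmbt2 cluster -0.0011 without outlier spots, each with 1 member left. Under the deposited gene totals miR-466h-3p reversed to -2.86 and miR-3070b-3p to -0.73. Both of these and the erythroid value come from carried-over totals. The cause was not tested for the values under quantile normalization or the counts from the authors' table. The other 331 list values stayed within the spot SD. They include 23 under each uniform scaling, which could not move on the relative scale. Against random lists under the same alternative, a ranking chosen after the results were seen, the Sfmbt2 cluster lay above and the MDSC list below the central 95% in all 15 alternatives that left at least 3 members. The uniform scalings among the 15 repeat the reported values by construction and are no separate check. Dim signal limits the 2-fold calls.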

Other observations

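All tests in this part were chosen after the results they bear on had been seen.

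Within the Sfmbt2 cluster the arms of the hairpins differed in what was detected. Of 25 names ending in 5p, 18 were detected on both arrays, all above the median of all miRNAs, with a median relative log2 ratio of 0.19. Of 26 names ending in 3p, miR-466h-3p was the 1 detected on both, at 1.87, and 3 more were detected with IL-6 only (miR-466f-3p, miR-466i-3p and miR-669p-3p, named after their values were seen), while 22 were detected on neither array. Against the dim array's lowest detected value, which is no firm lower limit, miR-466f-3p was 2.96-fold and miR-466i-3p 2.99-fold higher. The split by arm was made after the values were seen and was not tested.

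Of 609 gene totals of detected miRNAs in the scanner files, 146 lay above the sum of their detected probes and 0 below it. Against the sum of all probes, which is the level used here, 146 lay above and 11 below. All 146 excesses over the detected probes equalled the total of the preceding detected miRNA in name order, which is consistent with a running total that was not reset. Different treatment of undetected probes was argued against, as the cause of the excesses, since 145 of the totals exceeded the sum of all their probes by over 3 errors. For let-7d-3p the gene total was 227 with IL-6 and 13.2 without, against probe sums of 12.8 and 13.2.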
